A study of Arabidopsis thaliana with 18 samples.

How the data were processed

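Gene counts were taken as the authors' counts per library, as integers, for 37336 gene rows in 18 libraries. Reads were aligned and counted by the authors with STAR 2.5.3 and TAIR10, and DESeq2 is also named, per the submitters' processing notes. The settings of each step, the strand setting and the gene annotation were not given in the sources used here, so overlapping genes on opposite strands could not be told apart. Besides the genes, each file held 5 rows of reads outside gene counts, which were kept out of every test. Per library these were 2.76 to 10.3% unmapped reads, 1.37 to 2.42% reads mapping to several places, 0.256 to 0.523% reads in no gene and 3.47 to 4.85% reads in more than 1 gene. Reads of close gene copies fall among those set apart, so counts of such families are uncertain. Gene symbols came from a reference annotation that matched 37051 rows (99.2%), used for names only, and no coordinates were used.

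Groups were taken from the labels, and all 18 libraries were used. The first-stage libraries, 12 in number, were fitted together with 1 coefficient per group, the later 6 in a fit of their own, and the difference of the NahG effects between accessions in a fit of all 18 in which each effect was taken within its own stage. The comparisons, the alternatives and the gene lists were set before the data were examined, except where a choice is said to have been made after. Genes were kept by edgeR's filterByExpr by group, leaving 20325, 20112 and 21061 genes. Libraries were scaled by TMM, and calls were made with edgeR's quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene comes from that test unless DESeq2 is named. The mid-parent was the mean of the parents' coefficients on the log scale. A gene outside both parents was called against either parent in the same direction. SE values were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. Except for Fisher's exact test, the p-values and intervals cover the spread between pools of plants or, for the low-count ratios, counting error alone. The p-values of Fisher's exact test cover neither, as they count genes as independent of each other.

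The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Log levels used a prior count of 2. Where a group had 0 reads, the fold was given against a floor of 3 counts over the whole group, between 0.0391 and 0.0489 CPM for the groups it was used for. In a single library 3 counts are 0.117 to 0.134 CPM in the first stage and 0.0924 to 0.107 in the later. Where it had 1 to 3 reads, the ratio was given with an exact 95% counting interval.

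Genes were named by a rule. In Ler NahG, in either C24 line, against the mid-parent and between the parents these were the 5 largest rises and 5 largest falls among called genes with a symbol and an average log2 CPM of at least 1. Every library of 1 group had to lie beyond every library of the other, except against the mid-parent. The 2 members of each list with the lowest adjusted p under 0.05 were added, and so were PR1, PR2, PR5, ICS1, SAG12, SAG13, PIF4, YUC8 and FLC throughout. Outside both parents the 3 highest and 3 lowest genes were named. Not every gene the rule allows was printed, and genes whose call ended on leaving out 1 library were mostly passed over. For the difference between accessions, values were given for genes named in the NahG comparisons.

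The 15 gene lists, 277 members in all, were written from general knowledge and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, with p adjusted over the lists of each comparison. The PValue of fry tests movement of a list in 1 direction and its Mixed value movement in either, and neither compares the list with other genes. The lists were salicylic acid response and systemic acquired resistance, salicylic acid synthesis and signalling, pattern-triggered immunity, jasmonate and ethylene defence, leaf senescence, photosynthesis and chlorophyll, auxin response and cell expansion, circadian clock, flowering time, inflorescence and floral organs, root, aliphatic glucosinolates, indole glucosinolates and camalexin, flavonoids and anthocyanins, and cold and abscisic acid response. Of the 15 circadian clock genes 0 were called in Ler NahG, 1 fell in either C24 line, 1 rose and 1 fell against the mid-parent, and 3 were lower in C24 than in Ler. Each of the clock calls in the lines and against the mid-parent ended on leaving out 1 library, and adjusted over the list alone 0 fell in line 3 and 0 rose against the mid-parent. Of 10 flowering time genes 1 fell in line 2 and 2 in line 3, and each of these calls also ended on leaving out 1 library. Of the 9 floral organ genes measured in the C24 lines 0 were called, and so were 0 of 2 root genes.

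The overlap of calls was tested with a one-sided Fisher's exact test on genes tested in both comparisons. Comparisons that share libraries were set against 20 simulations of unchanged groups, in which genes varied independently of each other. A shoot-apex score was written after the levels of STM and KNAT1 had been seen. It was the mean log2 CPM of those genes of a list of 10 that passed the filter in the fit of all 18 libraries. The alternatives tried were DESeq2, RLE size factors, no filter beyond 1 count, a 2-fold minimum, leaving out each library, the replicate number as a block, fits of the compared groups alone, fits of all 18 libraries, and summed parent libraries. The shoot-apex score as a covariate, thinned later libraries and the comparison of the lines with separate C24B libraries were added after the data were seen.

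The procedure was tested on simulated data with 50 genes changed at each of 1.5, 2, 4 and 8-fold. In the design of Ler NahG it recovered 28, 68, 96 and 96% of them and called 12 unchanged genes, where DESeq2 recovered 44, 76, 98 and 94% and called 39. In the design of line 2 it recovered 8, 58, 88 and 92% with 12 unchanged genes called, where DESeq2 recovered 20, 66, 88 and 92% with 45. For the mid-parent it recovered 42, 76, 94 and 94% with 7 unchanged genes called. A simulated senescence list lowered 4-fold had a camera adjusted p = 6.1e-71, adjusted p = 6.1e-07 with an estimated correlation and adjusted p = 9.9e-10 with fry, and 0 of 14 other lists were called. The simulated genes varied independently of each other, so these values do not show how the list tests perform on correlated genes. Transgene reads, splicing and allele-specific reads were not analysed here.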

Results

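RNA was sequenced from whole rosettes of Arabidopsis thaliana at 21 days, grown with 16 h of light and 8 h of dark at 21 °C and moved to soil at day 14. Each library was made from a pool of 6 to 10 plants. The plants were the accessions C24 and Ler, their F1 hybrid C24 x Ler, and transgenic plants of either accession carrying NahG, a bacterial salicylate hydroxylase that degrades salicylic acid, a hormone of defence and leaf ageing. A first sequencing stage held C24, Ler, Ler NahG and C24 x Ler with 3 libraries each. A later stage held C24 NahG line 2, C24 NahG line 3 and a separate set of C24 controls, called C24B, with 2 libraries each. The first 12 libraries held 22446656 to 25706088 reads counted to genes and the later 6 held 28132721 to 32465711. Levels are given as CPM, reads scaled for depth and composition, ± SD over the libraries of a group, and log2 fold changes with their SE and the adjusted p of edgeR's quasi-likelihood test. The p-values of that test measure the spread between these pools of plants. Fold changes were taken only between libraries of the same stage.

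PR1, whose transcription depends on salicylic acid, checked the labels of the transgenic plants. It stood at 915 ± 249 CPM in C24B (n = 2), 0.471 ± 0.073 in C24 NahG line 2 (n = 2) and 0.339 ± 0.0429 in C24 NahG line 3 (n = 2). In Ler it stood at 12.7 ± 13.7 CPM (n = 3) and in Ler NahG at 1.29 ± 0.425 (n = 3). Every NahG library lay below every library of its own control group. Transcripts of the transgene itself were not analysed here.

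**Figure D1:**
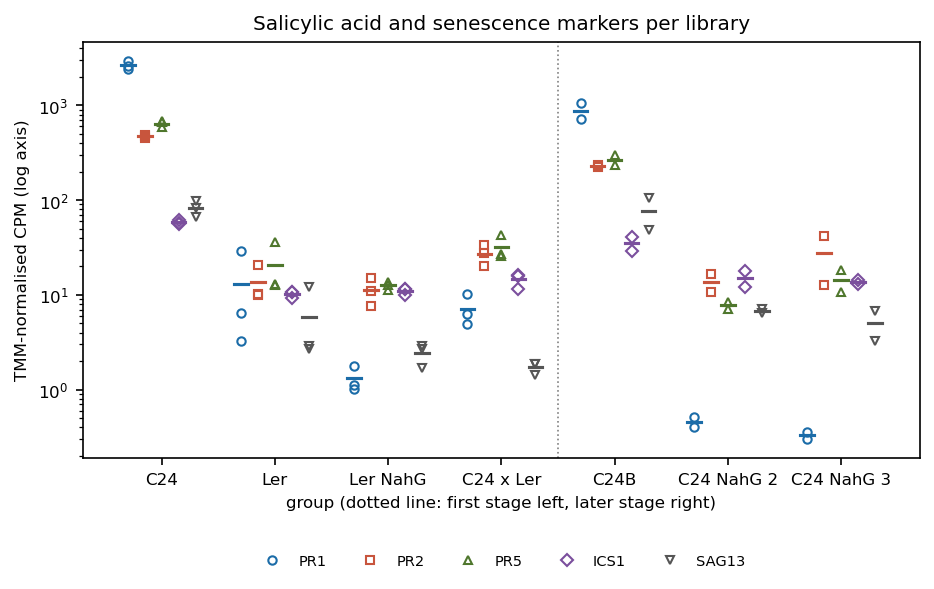
Levels of PR1, PR2, PR5, ICS1 and SAG13 in each of the 18 libraries, as CPM on a log axis, with points for libraries and bars for group means. PR1 lay between 2440 and 2940 CPM in the C24 libraries and between 0.301 and 0.51 CPM in the libraries of both C24 NahG lines.

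The first comparison asked which genes change with NahG in Ler, as the data hold no measure of salicylic acid itself. In Ler NahG, ECS1 (AT1G31580), which encodes a cell wall protein, fell by 6.72 on the log2 scale (SE 0.40, adjusted p = 1.6e-05), from 132 ± 62.5 to 1.23 ± 0.355 CPM. WRKY54 (AT2G40750), a transcription factor of the salicylic acid response, fell by 6.40 (SE 0.59, adjusted p = 0.00025). PCC1 (AT3G22231), a gene controlled by pathogens and the circadian clock, fell by 6.11 (SE 0.47, adjusted p = 9.2e-05), and ANK (AT5G54610), an ankyrin repeat protein, fell by 5.75 (SE 0.42, adjusted p = 7.1e-05). WRKY38 (AT5G22570), another WRKY factor, had 44 reads in Ler and 0 in Ler NahG and was at least 14-fold lower against a floor of 3 counts over the group, and its call ended without any 1 of the 3 Ler NahG libraries, with adjusted p between 0.062 and 0.072. XTH24 (AT4G30270), a xyloglucan-modifying enzyme of the cell wall, rose by 0.59 on the log2 scale (SE 0.081, adjusted p = 0.0057), and this call was lost in a fit of Ler and Ler NahG alone, with adjusted p = 0.15.

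Of the 23 measured members of the salicylic acid response list, 9 fell and 0 rose in Ler NahG, 15 fell when adjusted over the list alone, and 14 fell with DESeq2. LURP1 (AT2G14560), a gene induced late in resistance to downy mildew, fell by 5.60 (SE 0.45, adjusted p = 1e-04), from 83.8 ± 47.5 to 1.71 ± 0.301 CPM, and AED1 (AT5G10760), an apoplastic protease, fell by 2.34 (SE 0.19, adjusted p = 1e-04). The list's median log2 fold change was −3.06, or −2.34 with the 2 members at 0 reads set at their bound. Its camera test gave adjusted p = 1.6e-28, and adjusted p = 0.074 with an estimated correlation. Of the 15 members of the salicylic acid synthesis and signalling list, 3 fell and 6 fell when adjusted over the list alone, among them the salicylic acid receptor gene NPR4 (AT4G19660), which fell by 1.16 (SE 0.10, adjusted p = 0.00016). That list had a camera adjusted p = 3.4e-05, and adjusted p = 0.18 with an estimated correlation.

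Several well-known markers did not pass the test in Ler NahG. PR1 had a log2 fold change of −3.28 (SE 0.72, adjusted p = 0.09), and was called by DESeq2 with adjusted p = 0.00046 and without Ler replicate 3 with adjusted p = 0.016. PR5 had −0.71 (adjusted p = 0.64), PR2 −0.27 (adjusted p = 0.89) and ICS1, the isochorismate synthase of the main route to salicylic acid, 0.11 (adjusted p = 0.89). The senescence marker SAG13 had −1.25 (adjusted p = 0.55). None of the 24 measured members of the leaf senescence list passed, 1 passed when adjusted over the list alone, and the list's median of 0.08 and mean of −0.15 differed in sign, with a camera adjusted p = 0.78. None of the 34 members of the photosynthesis list passed singly, while the list as a whole stood higher with a camera adjusted p = 1.2e-06, and adjusted p = 0.71 with an estimated correlation. The auxin and cell expansion list stood higher as a list with 0 of 31 members called, 3 rising when adjusted over the list alone, a camera adjusted p = 3.1e-05, and adjusted p = 0.14 with an estimated correlation. The cold and abscisic acid list of 17 members had 0 calls and a camera adjusted p = 0.00084 upward, and adjusted p = 0.43 with an estimated correlation. The aliphatic glucosinolate list of 17 members had 0 calls and a camera adjusted p = 0.02 upward, and adjusted p = 0.71 with an estimated correlation. The pattern-triggered immunity list had 0 of 13 members called and the jasmonate and ethylene list 1 of 22, a call that ended on leaving out any 1 of several libraries.

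In all, 120 of 20325 genes differed between Ler NahG and Ler, 18 higher and 102 lower, and 1647 had an unadjusted p under 0.05. DESeq2 called 267 genes, 68 higher and 199 lower, and a fit of the compared groups alone called 21. The count was 45 without Ler NahG replicate 1, 68 without replicate 2 and 69 without replicate 3. The split was 55 higher and 96 lower without Ler replicate 1, and 6 and 129 without Ler replicate 2. The shoot-apex gene STM ranged from 9.89 to 49.1 CPM over the Ler libraries and from 8.83 to 44.5 over the Ler NahG libraries, and 0 of 8 measured shoot-apex markers, a list chosen after the values of some of them were seen, were called between these groups. WUS, also on that list, ranked the libraries of either group in the opposite order to STM.

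The next comparison put the same question in C24, with 2 independent NahG lines against C24B. PR1 fell by 10.91 on the log2 scale in line 2 (SE 0.32, adjusted p = 8.5e-06) and fell by 11.38 in line 3 (SE 0.33, adjusted p = 7.9e-06). LURP1 fell by 10.73 (SE 0.31, adjusted p = 8.5e-06) and fell by 11.68 (SE 0.33, adjusted p = 7.9e-06), from 1020 ± 152 CPM in C24B, and PCC1 fell by 9.62 (SE 0.26, adjusted p = 8.5e-06) and fell by 11.02 (SE 0.29, adjusted p = 7.9e-06). PCR1 (AT1G14880), named for cadmium resistance, fell by 10.37 in line 2 (SE 0.39, adjusted p = 2.5e-05) and kept 1 read in line 3 against 13131 in C24B, a ratio of 14200 with a 95% counting interval of 2550 to 561000. WRKY38 had 2 reads in line 2 and 1 in line 3 against 2435 in C24B, ratios of 1360 (375 to 11200) and 2630 (472 to 104000).

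All 23 members of the salicylic acid response list fell in either line, with the same 23 when adjusted over the list alone. Camera gave adjusted p = 2.1e-24 in line 2 and 1e-21 in line 3, against adjusted p = 0.11 and adjusted p = 0.13 with an estimated correlation. PR2, a beta-glucanase, fell by 4.09 in line 2 (SE 0.53, adjusted p = 0.0033) and fell by 3.08 in line 3 (SE 0.51, adjusted p = 0.0087), and PR5, a thaumatin-like protein, by 5.12 (SE 0.29, adjusted p = 9.5e-05) and fell by 4.21 (SE 0.28, adjusted p = 0.00013). Of the 15 members of the salicylic acid synthesis and signalling list, 11 fell and 1 rose in line 2, and 11 fell and 2 rose in line 3. Adjusted over the list alone, 12 fell and 2 rose in either line. For this list camera's adjusted p was 4.5e-06 in line 2 and 1.4e-05 in line 3, against adjusted p = 0.34 and adjusted p = 0.29 with an estimated correlation. CBP60G, a transcription factor that activates ICS1, fell by 1.96 in line 2 (SE 0.15, adjusted p = 0.00025) and fell by 2.35 in line 3 (SE 0.15, adjusted p = 0.00012), and NPR4 fell by 2.12 (adjusted p = 0.00017) and fell by 2.22 (adjusted p = 0.00012). ICS1 fell by 1.24 in line 2 (adjusted p = 0.015) and fell by 1.36 in line 3 (adjusted p = 0.0091), calls that ended without line 2 replicate 1 (adjusted p = 0.11), without line 3 replicate 1 (adjusted p = 0.1) and without line 3 replicate 2 (adjusted p = 0.094).

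Part of the leaf senescence list fell in the C24 lines. Of 25 measured members, 12 fell in line 2 and 15 in line 3 and 0 rose, against 20 and 18 falling when adjusted over the list alone. In either line camera's adjusted p was 1.9e-08, against adjusted p = 0.33 in line 2 and adjusted p = 0.29 in line 3 with an estimated correlation. YLS3, a gene that rises in yellowing leaves, fell by 2.31 in line 2 (SE 0.17, adjusted p = 0.00025) and fell by 2.48 in line 3 (SE 0.18, adjusted p = 0.00016). SAG13 fell by 3.53 (SE 0.43, adjusted p = 0.0023) and fell by 3.94 (SE 0.44, adjusted p = 0.0014), and NAC016, a senescence transcription factor, fell by 1.77 (SE 0.18, adjusted p = 0.00088) and fell by 1.67 (SE 0.17, adjusted p = 0.001). SAG12, a cysteine protease of ageing leaves, had 160 reads in C24B and 0 in either line, at least 59.4-fold and 57.7-fold lower, but the C24B libraries stood at 0.827 and 4.23 CPM and DESeq2 gave adjusted p = 0.28 and adjusted p = 0.23. The 3 first-stage C24 libraries, of the same accession and age, also had 0 reads of SAG12. Among the libraries of that accession it was therefore read only in C24B. Without 1 of the line's own libraries the SAG12 adjusted p was 0.13 and 0.14 in line 2, and 0.12 and 0.16 in line 3, and in line 2 it was 0.056 and 0.053 without the first and the second line 3 library. In the 34 photosynthesis genes 0 were called in either line, with medians of −0.22 and −0.25.

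Of 14 pattern-triggered immunity genes, 6 fell in either line and 0 rose, with 6 in line 2 and 9 in line 3 when adjusted over the list alone. Camera gave adjusted p = 0.00043 in line 2 and 6.8e-05 in line 3, against adjusted p = 0.33 and adjusted p = 0.29 with an estimated correlation. The chitin receptor gene CERK1 fell by 1.35 (SE 0.11, adjusted p = 0.00038) and fell by 1.39 (SE 0.11, adjusted p = 3e-04), and NHL10 fell by 5.12 in line 3 (SE 0.52, adjusted p = 9e-04). In the jasmonate and ethylene list 3 of 22 members rose and 2 fell in either line, with 4 rising and 2 falling in line 2 and 5 rising and 3 falling in line 3 when adjusted over the list alone. The vegetative storage protein genes VSP1 and VSP2 were among those that rose. VSP1 rose from 178 ± 0.906 CPM in C24B to 997 ± 131 in line 2 and 1100 ± 81.5 in line 3, by 2.48 (SE 0.16, adjusted p = 0.00014) and 2.62 (SE 0.16, adjusted p = 0.00011). VSP2 rose by 2.27 (adjusted p = 0.00052) and 2.57 (adjusted p = 0.00028), though these neighbouring genes are close copies and the split of reads between them is uncertain.

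Genes of aliphatic glucosinolates, defence compounds made from methionine, rose in 9 of 16 cases in line 2 and 12 of 16 in line 3, and 14 in either line when adjusted over the list alone. The camera adjusted p was 1.9e-08 in line 2 and 4.6e-09 in line 3, against adjusted p = 0.34 and adjusted p = 0.29 with an estimated correlation. The sulfotransferase gene SOT18 rose by 0.79 in line 2 (SE 0.13, adjusted p = 0.011), with adjusted p = 0.084 without line 2 replicate 1 and 0.07 without line 2 replicate 2. In the indole glucosinolate and camalexin list 2 of 11 members rose and 7 fell in either line, and 3 rose and 7 fell when adjusted over the list alone, with a camera adjusted p = 0.052 and 0.06. Among them CYP71A13, of camalexin synthesis, fell by 3.00 in line 2 (SE 0.19, adjusted p = 0.00014) and fell by 5.13 in line 3 (SE 0.23, adjusted p = 3.5e-05), while CYP79B3, which makes indole-3-acetaldoxime, rose by 1.35 in line 2 (SE 0.15, adjusted p = 0.0018). Flavonoid and anthocyanin genes rose in 1 of 14 cases in line 2 and 4 in line 3, and in 3 and 11 when adjusted over the list alone. DESeq2 called 7 of them higher in line 3. The call in line 2, of UF3GT, ended without any 1 of the NahG libraries of either line. In line 3 the calls of PAP1 and UF3GT ended without either line 3 library. Over this list camera's adjusted p was 0.00023 and 6.8e-05, against adjusted p = 0.36 and adjusted p = 0.37 with an estimated correlation. The auxin list had 1 member falling and 0 rising in line 2, and 0 falling when adjusted over the list alone, and 3 rising in line 3, with a camera adjusted p = 0.016 and 0.017 upward, against adjusted p = 0.33 and adjusted p = 0.29 with an estimated correlation. The fall in line 2 ended without either line 2 library and without line 3 replicate 2. Of the rises in line 3, IAA1 and IAA5 ended without either line 3 library, with adjusted p between 0.11 and 0.23, and IAA5 also without C24B replicate 1 or either line 2 library. Of 16 cold and abscisic acid genes 1 fell in line 2, a call that ended without either line 2 library or C24B replicate 1, and 5 fell and 1 rose in line 3. The rise in line 3, of COR15A, ended without line 3 replicate 1, and the fall of ABI1 there ended without line 3 replicate 2.

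Most of the largest rises were of genes outside the lists. CSLA01, of the mannan synthase family, rose by 3.31 in line 2 (SE 0.23, adjusted p = 0.00018) and by 2.89 in line 3 (SE 0.23, adjusted p = 0.00026). The sulfotransferase gene ST4B rose by 2.83 (adjusted p = 0.0036) and by 3.15 (adjusted p = 0.0019). The lipid transfer protein gene LTP4 rose by 4.16 in line 2 (SE 0.31, adjusted p = 0.00025), and AZI1, of systemic immunity, by 2.73 in line 3 (SE 0.27, adjusted p = 0.00081). THI2.1, a thionin of the jasmonate and ethylene list, rose by 2.73 in line 2 (SE 0.52, adjusted p = 0.018) and 2.68 in line 3 (SE 0.52, adjusted p = 0.018). The adjusted p of THI2.1 was 0.13 in line 2 without its replicate 1 and 0.13 in line 3 without its replicate 2.

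In line 2, 1651 of 20112 genes were called, 224 higher and 1427 lower, and in line 3 2062, 420 higher and 1642 lower. With both lines in 1 contrast 2652 were called, 574 higher and 2078 lower. DESeq2 gave 556 higher and 1745 lower in line 2, 880 higher and 2068 lower in line 3, and 1135 higher and 2335 lower for the lines together. The C24B libraries differed from each other in shoot-apex genes, with STM at 0.451 CPM in replicate 1 and 21.1 in replicate 2, while it stood at 22.7 and 27.3 CPM in line 2 and at 22.1 and 38.4 in line 3. Without C24B replicate 1 the counts were 1687 in line 2, 1937 in line 3 and 2168 together. Without C24B replicate 2 they were 4268, 5324 and 5558, and the balance changed, with 2064 higher and 2204 lower in line 2, 2506 and 2818 in line 3, and 2564 and 2994 together, so the printed split depends on 1 control library. Line 2 gave 645 without its replicate 1 and 658 without its replicate 2, and line 3 gave 801 (79 higher, 722 lower) and 611 (49 higher, 562 lower). The lines together gave 1494 without line 2 replicate 2, 1653 without line 3 replicate 1, 1415 without line 3 replicate 2 and 1737 without line 2 replicate 1.

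Between line 2 and line 3, 0 genes were called by edgeR's test, with a lowest adjusted p of 0.473 and 590 genes at an unadjusted p under 0.05. DESeq2 called 13. The count was 4 without C24B replicate 1, 4 without C24B replicate 2 and 1 without line 3 replicate 1. It was 13 without a filter on low counts, 3 in a fit of the compared groups alone and 1 in a fit of all 18 libraries. Of the calls in line 2, 1266 of 1427 lower genes were also lower in line 3 and 176 of 224 higher genes also higher, where independent lists would share 117 and 4.68. The lines share their C24B libraries, and in 20 simulations of unchanged groups against shared controls at most 1 lower and 2 higher genes were shared. Genes varied independently in these simulations. They do not allow for many genes shifting together between libraries of a group, so the simulated sharing may be too low. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.92 against a simulated 0.51 (0.49 to 0.54), and the covariance was 0.752 against 0.0582, a difference of 0.694. To share no control, and chosen after seeing the data, line 2 was also set against 1 C24B library and line 3 against the other. With 1 control library in each fit, the spread came from the NahG libraries alone, so the calls below do not cover the spread between control pools. With line 2 against replicate 1, 1153 lower and 273 higher genes were shared, where independent lists would share 163 and 40.4, and the covariance was 0.703. With line 2 against replicate 2 they were 1165 and 157, where 198 and 28.7 would be shared, and the covariance was 0.672.

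Whether the NahG effect differed between the accessions was tested directly, as the mean effect in the C24 lines minus the effect in Ler. PR1 differed by −7.85 on the log2 scale (SE 1.1, adjusted p = 0.00042), LURP1 by −5.59 (SE 0.64, adjusted p = 0.00011) and PCR1 by −9.55 (SE 0.73, adjusted p = 3.9e-06), all lower in C24. VSP1 differed by 2.82 (SE 0.16, adjusted p = 2.1e-07) and YLS3 by −2.46 (SE 0.31, adjusted p = 0.00023). ECS1, lowered in Ler NahG as described, had a difference of −0.18 (SE 0.66, adjusted p = 0.9). Of the 23 salicylic acid response genes 10 fell further in C24 and 0 in Ler, with 13 when adjusted over the list alone. That list had a camera adjusted p = 1.5e-16, against adjusted p = 0.12 with an estimated correlation. Of 25 leaf senescence genes 12 fell further in C24, with 15 when adjusted over the list alone, a camera adjusted p = 9.3e-09, and adjusted p = 0.17 with an estimated correlation.

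Of 21061 genes, 1854 had a NahG effect that differed between the accessions, 427 with a higher and 1427 with a lower value in C24. DESeq2 gave 1111 and 1687. The count was 812 without C24B replicate 1 (50 higher, 762 lower), 3140 without C24B replicate 2 (1356 higher, 1784 lower), 3533 without Ler replicate 1 (1213 higher, 2320 lower), 1221 without Ler replicate 2 and 1151 without Ler replicate 3. STM stood at 0.451 CPM in C24B replicate 1, and with a shoot-apex score as a covariate, chosen after seeing the data, the count was 652. The C24 and Ler terms come from different sequencing stages, each a difference within its own stage. They also come from different transgenic plants, whose level of the transgene was not analysed, so accession and transgenic line cannot be told apart.

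The genes lower in Ler NahG were compared with those lower in the C24 lines together, 2 comparisons with no library in common. Of 99 genes lower in Ler NahG and tested in both, 93 were lower in the C24 lines, where 10.3 would be shared by independent lists (one-sided Fisher's exact test, p = 4.5e-84). Fisher's test counts genes as independent, so its p-values do not measure the spread between pools. Of the 16 higher in Ler NahG, 3 were higher in the C24 lines, where 0.466 would be shared (one-sided Fisher's exact test, p = 0.01).

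**Figure D2:**
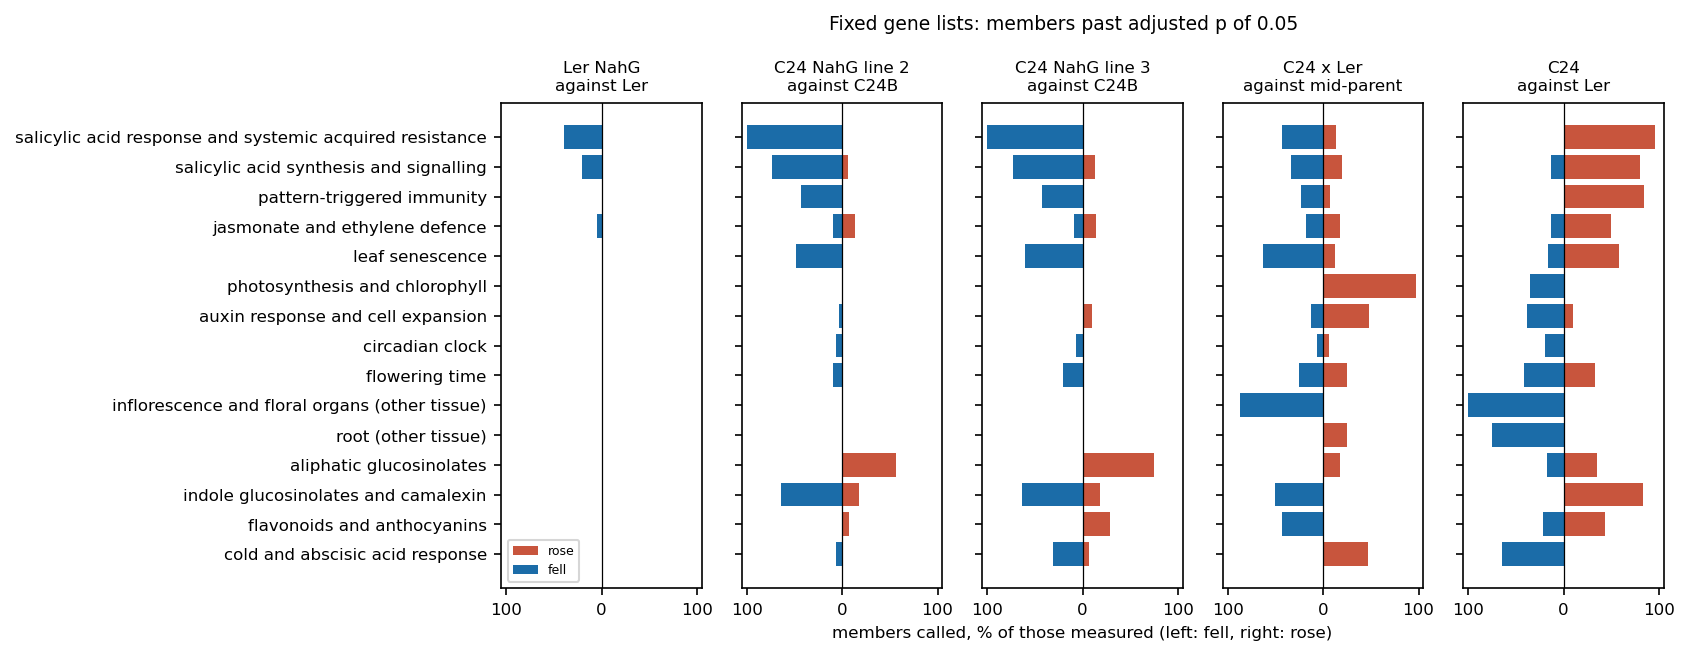
Percent of measured members of each of the 15 fixed gene lists called higher or lower in 5 comparisons, with bars to the right for higher and to the left for lower. In the C24 NahG lines all 23 salicylic acid response genes were lower, and in the hybrid against the mid-parent 33 of 34 photosynthesis genes were higher.

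The parents were compared to place the hybrid between them. PR1 stood at 2600 ± 252 CPM in C24 and 12.7 ± 13.7 in Ler, higher in C24 by 7.69 on the log2 scale (SE 0.72, adjusted p = 5.2e-06). ICS1 was higher in C24 by 2.5 (SE 0.12, adjusted p = 3.7e-08), CBP60G by 5.27 (SE 0.26, adjusted p = 3e-08) and SAG13 by 3.81 (SE 0.47, adjusted p = 4.4e-05). FLC, a repressor of flowering, had 1739 reads in C24 and 3 in Ler, a ratio of 550 (188 to 2670), while SOC1, a promoter of flowering, was lower in C24 by 3.14 (log2 fold change −3.14, SE 0.10, adjusted p = 1.1e-09). CSA1, a resistance gene, was higher in C24 by 9.54 (SE 0.25, adjusted p = 2e-10), and RPM1, another, had 0 reads in C24 and was at least 319-fold lower there. The adjoining side-chain genes of aliphatic glucosinolates went opposite ways, AOP2 higher in C24 by 8.41 (SE 0.14, adjusted p = 6.6e-12) and AOP3 with a log2 fold change of −9.98 (SE 0.17, adjusted p = 6.6e-12).

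Of 23 salicylic acid response genes 22 were higher in C24 than in Ler and 0 lower, and 22 were higher and 1 lower when adjusted over the list alone. The camera adjusted p was 3.1e-13, against adjusted p = 0.16 with an estimated correlation. DLO1, which hydroxylates salicylic acid, was higher by 7.77 (SE 0.44, adjusted p = 1e-07) and AED1 by 4.58 (SE 0.19, adjusted p = 8.9e-09). Of 15 salicylic acid synthesis and signalling genes 12 were higher and 2 lower, also when adjusted over the list alone, with a camera adjusted p = 7.1e-06, and adjusted p = 0.16 with an estimated correlation. Of 13 immunity genes 11 were higher and 0 lower, with a camera adjusted p = 1.2e-05, and adjusted p = 0.23 with an estimated correlation. Of 24 leaf senescence genes 14 were higher and 4 lower, and 14 and 5 when adjusted over the list alone, with a camera adjusted p = 0.011, and adjusted p = 0.35 with an estimated correlation. NAC016 was higher in C24 by 4.04 (SE 0.19, adjusted p = 2.3e-08) and YLS5 by 2.75 (SE 0.15, adjusted p = 7.6e-08). Of 12 indole glucosinolate and camalexin genes 10 were higher and 0 lower, with a camera adjusted p = 2.4e-05, and adjusted p = 0.23 with an estimated correlation.

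Some photosynthesis, auxin and cold genes were lower in C24 than in Ler. Of 34 photosynthesis genes 12 were lower and 0 higher, also when adjusted over the list alone, with a camera adjusted p = 0.0016, and adjusted p = 0.56 with an estimated correlation. LHCB1.1, of the light-harvesting antenna, had a log2 fold change of −2.06 (SE 0.25, adjusted p = 3.6e-05), with reads shared among close copies in that family. Of 31 auxin and cell expansion genes 12 were lower and 3 higher, also when adjusted over the list alone, with a camera adjusted p = 0.011, and adjusted p = 0.24 with an estimated correlation. Of 17 cold and abscisic acid genes 11 were lower and 0 higher, with a camera adjusted p = 5.9e-06, and adjusted p = 0.16 with an estimated correlation, and COR15A, which protects chloroplasts in the cold, had −3.17 (SE 0.16, adjusted p = 3.3e-08). VSP1 had −4.43 (SE 0.12, adjusted p = 3.3e-10). All 8 floral organ genes, markers of another tissue, were lower in C24, with a camera adjusted p = 6.9e-06, and adjusted p = 0.16 with an estimated correlation. The floral identity gene SEP3 stood at 1.22 ± 0.435 CPM in C24 and 25.9 ± 7.83 in Ler. CYP704B1, which acts in pollen wall formation, had 0 reads in C24 and was at least 688-fold lower there. Of 12 flowering time genes 4 were higher and 5 lower. Of 4 measured root markers 3 were lower in C24, including IRT1, the iron transporter, with 3 reads in C24 and 117 in Ler, a ratio of 41.1 (13.7 to 202).

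In all, 8629 of 20325 genes differed between C24 and Ler, 4602 higher and 4027 lower in C24. Reads of both accessions and the hybrid were aligned to the same genome, TAIR10. Differences in counts between them can therefore mix expression with genes missing from an accession or reads that align less well, which was not tested.

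The hybrid was compared with the mean of its parents' log levels, the question being where the F1 departs from the mid-parent level. PR1 fell by 4.67 on the log2 scale (SE 0.62, adjusted p = 0.00048), to 7.09 ± 2.75 CPM, and SAG13 fell by 3.65 (SE 0.49, adjusted p = 0.00054), to 1.7 ± 0.251 CPM. The light-harvesting gene LHCB3 rose by 0.74 (SE 0.16, adjusted p = 0.0062), with 2420 ± 123 CPM in C24, 3620 ± 885 in Ler and 4950 ± 57.3 in the hybrid. The cold-regulated gene COR15A rose by 1.93 (SE 0.12, adjusted p = 1.7e-06). The shoot-apex genes STM and KNAT1 fell by 6.10 (SE 0.83, adjusted p = 0.00056) and fell by 5.96 (SE 1.1, adjusted p = 0.003), with STM at 24.3 ± 1.43 CPM in C24, 32.8 ± 20.4 in Ler and 0.399 ± 0.302 in the hybrid (n = 3 each).

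Photosynthesis genes rose in 33 of 34 cases, and in 34 when adjusted over the list alone, in the same hybrid libraries in which STM lay at 0.103, 0.396 and 0.707 CPM. The camera adjusted p was 1.1e-12, against adjusted p = 0.35 with an estimated correlation. PSBO2, of the oxygen-evolving complex, rose by 0.66 (SE 0.14, adjusted p = 0.0065). Against C24 alone 32 of the 34 rose (camera adjusted p = 1e-12, and adjusted p = 0.3 with an estimated correlation), and against Ler alone 9 rose (camera adjusted p = 5.7e-05, and adjusted p = 0.79 with an estimated correlation), with 34 and 5 when adjusted over the list alone. Against Ler the 9 became 5 with RLE size factors and 18 with DESeq2. Of 31 auxin and cell expansion genes 15 rose and 4 fell, and 17 rose and 4 fell when adjusted over the list alone, with a camera adjusted p = 0.0043, and adjusted p = 0.35 with an estimated correlation. Among those that fell were GH3.3, which fell by 2.31 (SE 0.22, adjusted p = 4.3e-05), and GH3.5, which fell by 3.15 (SE 0.35, adjusted p = 0.00015). Both conjugate auxin to amino acids. PIF4, a factor of warm-temperature growth, rose by 0.50 (SE 0.12, adjusted p = 0.013), with 0.29 and adjusted p = 0.059 without hybrid replicate 3. Of 17 cold and abscisic acid genes 8 rose and 0 fell, also when adjusted over the list alone, with a camera adjusted p = 0.00027, and adjusted p = 0.35 with an estimated correlation.

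Leaf senescence genes fell in 15 of 24 cases and rose in 3, and fell in 15 and rose in 4 when adjusted over the list alone. The camera adjusted p was 0.0012, against adjusted p = 0.35 with an estimated correlation. SAG14, a blue copper protein, fell by 2.13 (SE 0.25, adjusted p = 0.00018), from 135 ± 25.2 CPM in C24 and 16 ± 6.77 in Ler to 10.6 ± 2.58. Against C24 16 senescence genes fell and 3 rose, and against Ler 6 fell and 5 rose. Of 23 salicylic acid response genes 10 fell and 3 rose against the mid-parent, and 13 fell and 4 rose when adjusted over the list alone, with a camera adjusted p = 0.0014, and adjusted p = 0.53 with an estimated correlation. PR5 fell by 1.83 (SE 0.31, adjusted p = 0.0023) and PR2 by 1.54 (SE 0.27, adjusted p = 0.0025). Against C24 20 of the 23 fell and 0 rose (camera adjusted p = 3.4e-12, and adjusted p = 0.15 with an estimated correlation), and against Ler 15 rose and 0 fell (camera adjusted p = 2.1e-05, and adjusted p = 0.75 with an estimated correlation). Of 15 salicylic acid synthesis and signalling genes 5 fell and 3 rose against the mid-parent, with ICS1 falling by 0.72 (SE 0.11, adjusted p = 0.00099) and its paralog ICS2 rising by 0.88 (SE 0.15, adjusted p = 0.0023). Of 13 immunity genes 3 fell and 1 rose. NHL10 had 1 read in the hybrid, against 1550 in C24 and 23 in Ler, ratios of 1240 (222 to 49000) and 19.4 (3.15 to 798).

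Of 12 indole glucosinolate and camalexin genes 6 fell and 0 rose against the mid-parent, also when adjusted over the list alone, with a camera adjusted p = 0.0014, and adjusted p = 0.39 with an estimated correlation. CYP79B2 fell by 1.68 (SE 0.23, adjusted p = 0.00062). Of 14 flavonoid and anthocyanin genes 6 fell and 0 rose, and 7 fell and 1 rose when adjusted over the list alone, with a camera adjusted p = 0.0014, and adjusted p = 0.35 with an estimated correlation. TT7, the flavonoid 3′-hydroxylase, fell by 2.08 (SE 0.27, adjusted p = 4e-04). Of 8 floral organ genes 7 fell, and 8 when adjusted over the list alone, with a camera adjusted p = 0.00033, and adjusted p = 0.35 with an estimated correlation. The floral identity gene AP1 stood at 0.3 ± 0.452 CPM in C24, 18.5 ± 4.09 in Ler and 0.0816 ± 0.0288 in the hybrid. Of 22 jasmonate and ethylene genes 4 rose and 4 fell, with AOS, of jasmonate synthesis, rising by 1.15 (SE 0.16, adjusted p = 0.00054) and VSP1 falling by 0.77 (SE 0.095, adjusted p = 0.00029). The aliphatic glucosinolate list had 3 of 17 members rising, a camera adjusted p = 0.026, and adjusted p = 0.64 with an estimated correlation.

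Against summed parent libraries, a mean of levels instead of logs, several of the log2 fold changes given above were over 1.5 times as large or as small. They were −7.51 for PR1, −3.34 for PR5, −3.12 for PR2, −1.19 for ICS1, −2.03 for VSP1 and 1.21 for COR15A.

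The largest rises against the mid-parent were of genes read almost only in 1 parent, where a mean of log levels lies far below a mean of levels. FLC rose by 3.87 (SE 0.25, adjusted p = 2.7e-06) with 22.6 ± 0.792 CPM in C24, 15 ± 1.28 in the hybrid and 3 reads in Ler. Against summed parent libraries its log2 fold change was 0.42 (adjusted p = 0.015). AOP3 rose by 4.59 (SE 0.1, adjusted p = 4.5e-10), or 0.62 against summed parents (adjusted p = 0.0039). CSA1 rose by 3.63 (SE 0.16, adjusted p = 1e-07), but stood at −0.13 against summed parents (adjusted p = 0.21), and AOP2 rose by 3.46 (SE 0.088, adjusted p = 7.4e-10), or 0.26 against summed parents (adjusted p = 0.11). MAF1, another repressor of flowering, rose by 2.76 (SE 0.1, adjusted p = 2.4e-08), with 0.494 ± 0.0836 CPM in C24, 14.7 ± 0.733 in Ler and 18.3 ± 1.33 in the hybrid, or 1.29 against summed parents (adjusted p = 0.00015).

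Against the mid-parent 5500 of 20325 genes were called, 3156 higher and 2344 lower, and against summed parents 5717, 2548 higher and 3169 lower. With summed parents 19 of the salicylic acid response genes fell and 0 rose, 18 of the senescence genes fell and 3 rose, 32 photosynthesis genes rose and 4 cold genes rose. In the indole glucosinolate and camalexin list 10 then fell, and in the jasmonate and ethylene list 7. With a 2-fold minimum 1701 genes were left, 515 higher and 1186 lower. The count was 2810 without hybrid replicate 1 and 3594 without hybrid replicate 2. Against C24 7433 genes were called, 3502 higher and 3931 lower. Against Ler 6149 were called, 3215 higher and 2934 lower, with 3996 without hybrid replicate 1, 4064 without Ler replicate 3 and 3949 in a fit of the compared groups alone. Most calls against Ler were lower instead with RLE size factors (2908 higher, 3069 lower), with DESeq2 (3209 and 3387), with a 2-fold minimum (995 and 1734), in the fit of the compared groups (1759 and 2190) and without Ler replicate 2 (2198 and 2238).

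The hybrid was above both parents in 793 genes and below both in 906. RLP38, a receptor-like protein, rose against C24 by 1.87 (SE 0.21, adjusted p = 6e-05) and against Ler by 2.24 (SE 0.22, adjusted p = 2.4e-05), and SCPL9, a serine carboxypeptidase-like protein, by 1.79 (SE 0.16, adjusted p = 1.3e-05) and 1.78 (SE 0.16, adjusted p = 1.6e-05). ECS1 rose by 4.39 (SE 0.33, adjusted p = 3.6e-06) and 1.5 (SE 0.29, adjusted p = 0.0026), to 373 ± 108 CPM. STM fell by 5.89 (SE 0.87, adjusted p = 0.00039) and fell by 6.32 (SE 0.86, adjusted p = 0.00031), and the transcription factor gene WRKY14 fell by 6.03 (SE 0.91, adjusted p = 0.00046) and fell by 5.73 (SE 0.92, adjusted p = 0.00088). Of the 8 measured shoot-apex markers, chosen after the values of some of them were seen, 6 fell against C24 and 8 against Ler. The 1699 genes became 523 with a 2-fold minimum, 32 above and 491 below. The count was 764 without hybrid replicate 1, 1039 without hybrid replicate 2, 1095 without C24 replicate 3, 2788 without Ler replicate 1 (1582 above and 1206 below), 1128 without Ler replicate 2 and 931 without Ler replicate 3.

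**Figure D3:**
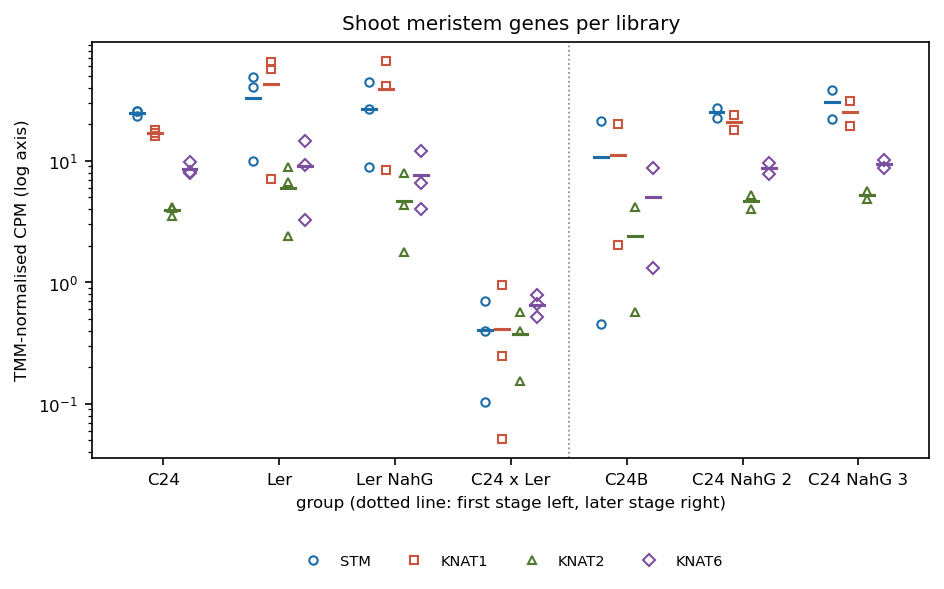
Levels of the shoot-apex genes STM, KNAT1, KNAT2 and KNAT6 in each of the 18 libraries, as CPM on a log axis, with points for libraries and bars for group means. STM lay between 0.103 and 0.707 CPM in the hybrid libraries and at 0.451 CPM in C24B replicate 1, and between 8.83 and 49.1 CPM in all others.

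The genes lower in the C24 NahG lines together were compared with those lower in the hybrid than in C24, in which no library is shared. Of 2039 genes lower in the lines and tested in both, 1265 were lower in the hybrid, where independent lists would share 402 (one-sided Fisher's exact test, p at most 1e-300), and 76 were higher. Of the same 2039 genes, 1608 were higher in C24 than in Ler, so a hybrid lying between its parents would also be lower than C24 in many of them. The numbers for independent lists, here and for Ler NahG below, do not allow for this difference between the parents. Nor do the Fisher p-values, which also count genes as independent. Of 569 genes higher in the lines, 130 were higher in the hybrid, where 95.3 would be shared (one-sided Fisher's exact test, p = 8.9e-05), and 75 were lower. Against the mid-parent 388 of the 2039 were lower, where 238 would be shared (one-sided Fisher's exact test, p = 6.3e-25), and 246 were higher. This overlap and that of Ler NahG with the mid-parent below use the mean of log levels. That mean lies below a mean of levels where the parents differ, and neither overlap was repeated with summed parents. Of the 102 genes lower in Ler NahG, 73 were lower in the hybrid than in C24, where 19.7 would be shared (one-sided Fisher's exact test, p = 2.8e-30). Against the mid-parent, which shares the Ler libraries, 15 of the 102 were lower, where 11.8 would be shared (one-sided Fisher's exact test, p = 0.19), and 37 were higher. The correlation of those fold changes across genes was 0.21 against 0.24 in simulations of unchanged groups with shared controls, and the covariance 0.0948 against 0.0271. Genes varied independently in these simulations too.

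**Figure D4:**
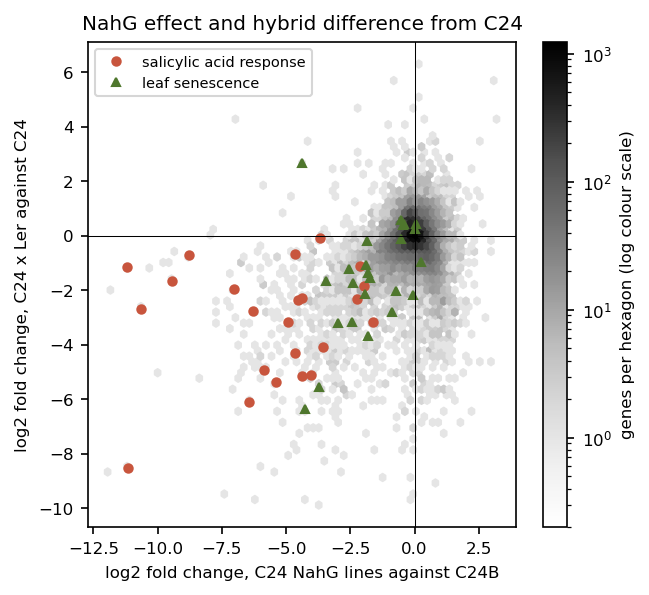
Log2 fold change of each gene in the C24 NahG lines together against C24B, on the horizontal axis, and in the hybrid against C24, on the vertical axis, as a density of genes with salicylic acid response genes as dots and senescence genes as triangles. All 23 salicylic acid response genes lay below 0 on the horizontal axis, and 20 were called lower on the vertical one.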

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

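The shoot-apex tests, the thinning and the test of standing levels were chosen only after the results they address had been seen, and the shoot-apex score after the levels of STM and KNAT1 were seen.

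The NahG effect differed between the accessions in 1854 genes, which drew attention as a difference between groups. Of the genes named in both accessions, those that differed were PR1 (−7.85 on the log2 scale, C24 minus Ler), LURP1 (−5.59), PCC1 (−4.19), PR5 (−3.94), PR2 (−3.30), SAG13 (−2.47), ICS1 (−1.40) and NPR4 (−1), all lower in C24, and THI2.1, a thionin of jasmonate defence, which was higher (5.12). THI2.1 fell by 2.41 in Ler NahG (SE 0.45, adjusted p = 0.037) and rose by 2.73 in line 2 (SE 0.52, adjusted p = 0.018), and both calls were fragile to the processing. Genes named in only 1 accession differed both ways, among them PCR1 (−9.55), YLS3 (−2.46) and CERK1 (−1.11), lower in C24, and ST4B (4.49), VSP1 (2.82), CSLA01 (2.58) and VSP2 (2.47), higher.

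Depth was weighed first for the far lower number of calls in Ler than in C24. With the later libraries thinned to the mean depth of Ler and Ler NahG, line 2 still had 1634 calls against 120 in Ler, so depth does not account for the gap. Unequal shoot-apex content among the Ler libraries could hide calls. With the shoot-apex score as a covariate the count in Ler was 238, against 1490 in line 2 under the same covariate, so what the score captures was not the whole cause. The listed markers did not agree on that content. In Ler replicates 1 to 3 STM stood at 9.89, 40.5 and 49.1 CPM and WUS, on the same list, at 2.1, 1.59 and 0.442. In Ler NahG STM stood at 26.9, 8.83 and 44.5 CPM and WUS at 1.05, 1.17 and 0.17. KNAT1, KNAT2 and KNAT6 followed STM in both groups. A lower standing level in Ler of the genes that NahG lowers would leave less to lose. Of the genes lower in the C24 lines together 78.9% (1608 of 2039) were higher in C24 than in Ler, against 23.2% of all 19547 genes, as that reading predicts. A gene could be called lower in the lines only where C24B expressed it, and the 23.2% was not matched for level. The selection itself thus favours this outcome, so the test cannot decide. Nor can it separate a low level of the hormone from other differences between the accessions. The accessions also differ in their transgenic plants, and as transgene reads were not analysed, a difference in NahG activity cannot be told apart. With the covariate the accession difference itself was 652 genes.

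Genes below both parents in the hybrid included STM and KNAT1, which mark the shoot apex. Of 900 such genes tested, 91.1% rose with the shoot-apex score within the groups other than the hybrid, against 48.8% of other genes. Within the first-stage groups alone the share was 73.6%, and within the later groups, which had no part in the hybrid calls, 94.2%. The later slopes rest almost wholly on 1 pair of libraries, C24B replicate 1 and replicate 2, with scores of −1.49 and 0.94, while the NahG libraries spanned 1.08 to 1.39. C24B replicate 1 shared the low shoot-apex genes but was no mislabelled hybrid, since 19 genes read in Ler and the hybrid but under 0.1 CPM in C24 stood there at a median of 0% of the hybrid level. Scaling was no cause for most, since 94.2% of the genes fell by more than the widest gap of 0.36 between scaling factors on the log2 scale. The slopes are consistent with less shoot apex in the hybrid rosettes lowering many of these genes (91.1%), but another difference between the C24B libraries would give such slopes too, and whether harvest or development lay behind it stays open.

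The same score predicted higher photosynthesis genes in the hybrid. From slopes within the other groups the list would differ by 0.94 on the log2 scale, where 0.63 was observed, and between C24B replicate 1 and replicate 2, of the same genotype, it differed by 0.53. Of its 34 genes 0% had a positive slope within the first-stage groups and 0% within the later groups, against 91.1% of the genes below both parents. Tissue content could therefore account for some or all of the rise of photosynthesis genes in the hybrid, which the data leave open. For the 793 genes above both parents 8.83% had a positive slope, with a predicted difference of 0.53 against 0.54 observed.

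The libraries of each comparison were also regrouped in every possible or sampled way. For 4 comparisons only 10 splits exist, too few to exclude chance. Ler NahG ranked 2 of 10 with 120 calls, where the highest other split had 1635, that of Ler replicate 1 with Ler NahG replicates 1 and 2 against the rest. That split set shoot-apex scores of 0.97, 1.4 and 1.01 against 1.95 and 1.86 in Ler replicates 2 and 3 and 1.71 in Ler NahG replicate 3. Whether shoot-apex content caused its calls was not tested. The hybrid against C24 ranked 1 with 7433 and a highest other of 0, the hybrid against Ler ranked 1 with 6149 and 0, and C24 against Ler ranked 1 with 8629 and 0. Against the mid-parent the real grouping ranked 2 of 100, with 5500 calls and 6491 in the highest other, which put C24 in the hybrid's place. Outside both parents it ranked 2 of 100, with 1699 and 3610, again with C24 in the hybrid's place. Most of these regroupings mix genotypes and so carry the parents' own differences as spread, so the ranks bear on differences among the genotypes and not on the hybrid's departure from its parents.

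Unmapped reads drew attention as data outside the gene counts, with a higher share in the C24 NahG lines than in C24B. They made up 8.8 and 10.3% in C24 NahG line 3 and 7.32 and 6.85% in line 2, against 6.7 and 6.02% in C24B. In Ler NahG they made up 2.89, 2.76 and 3.28%, against 2.99, 2.89 and 3.77% in Ler, so the other NahG group was not higher than its controls. Their sequence was not examined here.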

How the results depend on the processing

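The shoot-apex covariate and the thinning were chosen after seeing the data, and for the changes below the cause was not tested unless stated. In the NahG comparisons and between the parents most calls kept the same direction throughout. Against the mid-parent most calls turned from higher to lower with summed parents (2548 and 3169) and with a 2-fold minimum (515 and 1186). Against Ler they turned with RLE size factors (2908 and 3069), DESeq2 (3209 and 3387), a 2-fold minimum (995 and 1734), a fit of the compared groups alone (1759 and 2190) and without Ler replicate 2 (2198 and 2238). Outside both parents they turned from below to above without Ler replicate 1 (1582 and 1206) and without hybrid replicate 3 (766 and 736).

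A 2-fold minimum leaves fewer genes by its construction, with 1013 in line 2, 1196 in line 3, 1284 for the lines together, 1701 for the mid-parent, 2641 for the hybrid against C24, 2729 against Ler, 3960 between the parents, 894 for the difference between accessions and 523 outside both parents. It left 97 in Ler NahG and 83 of the 93 genes lower with NahG in both accessions. DESeq2 gave 267 in Ler NahG, 2798 for the difference between accessions and 13 between the lines. Without a filter there were 2504 in line 2, 3325 in line 3 and 13 between the lines. Fits of the compared groups alone gave 21 in Ler NahG, 3949 for the hybrid against Ler and 3 between the lines. Fits of all 18 libraries gave 2631 in line 2, 3352 in line 3 and 1 between the lines. The shoot-apex covariate gave 238 in Ler NahG and 652 for the difference between accessions.

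Leaving out 1 library gave 45 to 151 calls in Ler NahG (68 and 69 without replicate 2 and 3 of Ler NahG), 2810 to 6771 for the mid-parent (3594 without hybrid replicate 2), 5578 to 8261 for the hybrid against C24, 3996 to 7608 against Ler (4064 without Ler replicate 3) and 7130 to 9131 between the parents. Outside both parents it gave 764 to 2788, with 1095 without C24 replicate 3, 1128 without Ler replicate 2, 931 without Ler replicate 3 and 1039 without hybrid replicate 2. Line 2 gave 645 to 4268 (658 without its replicate 2), line 3 gave 611 to 5324 (801 without its replicate 1) and the lines together 1415 to 5558, with 1737 and 1494 without line 2 replicate 1 and 2 and 1653 without line 3 replicate 1. Between the lines it gave 0 to 4, with 1 without line 3 replicate 1. The difference between accessions gave 812 to 3533, with 1221 without Ler replicate 2, 1151 without Ler replicate 3 and 3140 without C24B replicate 2.

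The replicate number as a block gave 114 in Ler NahG, 5341 for the mid-parent, 2294 in line 2, 3069 in line 3, 3811 for the lines together and 2191 for the difference between accessions, and moved no total by over 1.5 times. The higher calls moved more, from 224 to 602 in line 2, from 420 to 992 in line 3 and from 574 to 1283 for the lines together. In the first stage 4 of 18 same-number pairs correlated above 0.1, so the numbers do not pair those libraries. In the later stage the correlation was 0.13 between C24B and either line and 0.02 between the lines, and 2 libraries per group give only 1 such value for each pair of groups, so pairing there was neither shown nor excluded. The block ended the calls of 2 named genes, ELF3 against the mid-parent (0.26, adjusted p = 0.071) and THI2.1 in Ler NahG (−2.38, adjusted p = 0.088).

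CSA1 turned from 3.63 to −0.13 against summed parents, which follows from a mean of logs against a mean of levels. For single genes 1357 outcomes were the same, 56 weaker and 2 stronger over the other alternatives, and 1643, 119 and 2 on leaving out libraries. With an estimated correlation 0 of 75 list tests passed, against 38 with the preset one, 37 with fry and 52 with its Mixed value, and list outcomes were the same in 142 cases, weaker in 54 and stronger in 29. Small changes were often missed, with 28% of simulated 1.5-fold changes recovered in Ler NahG and 8% in line 2. Depth limited the counts little in the later stage, where thinning left 1634 calls in line 2, 2048 in line 3 and 2573 for the lines together.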

Other observations

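Genes read in only 1 parent, chosen after their values were seen, stood at different levels in the hybrid by parent. Only members of the shoot-apex, floral organ and root lists were left out, so other genes of those tissues could remain. Whether such a gene was silent or missing in the other parent, or its reads failed to align there, was not tested. Of 51 such genes over 5 CPM in C24 with at most 3 reads in Ler, the hybrid stood at a median of 0.433 of the C24 level (quartiles 0.293 and 0.519). There 7 were under 0.1 of it and 39 lay from 0.25 to 1. Of 76 such genes over 5 CPM in Ler with at most 3 reads in C24, the median was 0.00189 of the Ler level (quartiles 0.000397 and 0.35). Here 53 were under 0.1 and 21 lay from 0.25 to 1. RPM1, with 0 reads in C24, stood at 12.6 ± 2.56 CPM in Ler and 10.3 ± 0.971 in the hybrid. CYP704B1, which acts in pollen wall formation, had 1959 reads in Ler, 0 in C24 and 2 in the hybrid. All 8 floral organ genes were also lower in the hybrid than in Ler, with a median of −4.52 on the log2 scale, a camera adjusted p = 3.4e-07, and adjusted p = 0.32 with an estimated correlation, as they were lower in C24 than in Ler, with a median of −4.79.

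The second library of C24 NahG line 3 held 428 CPM of mitochondrial ribosomal RNA (ATMG00020), against 7.13 to 33.6 CPM in the others, and the highest share of unmapped reads, 10.3%. C24 replicate 1 had 9.32% unmapped reads.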
